A study of Homo sapiens with 4 samples.

How the data were processed

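RNA from HPNE and Capan1 cells, untreated or kept in cigarette smoke extract (CSE), had been sequenced as 1 library per line and treatment, 4 libraries in all. Per the labels' protocols, RNA was isolated with the mirVana kit, had an RNA integrity number of 10 in every library, and was made into libraries with the Illumina TruSeq RNA kit. The labels describe extract from 2 research cigarettes in 10 ml of medium, at 8 min and about 0.8 mg of nicotine per cigarette, taken as full strength. They give 40 passages of 2 days each, with cells reseeded in 100 mm plates, 24 h of growth before treatment and 48 h in extract. Whether the untreated cells were passaged in parallel is not given in the sources used here.

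For each line the authors deposited a table of genes with the RPKM of both libraries, the log2 fold change between them and a flag for direction. Per the submitters' processing notes, FastQC and edgeR were used and the genome build was hg19. The aligner, the counting tool, its use of strand and the gene annotation are not given in the sources used here. The deposited RPKM values, multiplied by gene length and library total, gave whole numbers of bases for 100% of values within a tolerance of 0.01, and the totals were multiples of 51 bases, which was taken as the read length. The total reads and the reads per gene given here are implied by those values. The bases of the listed genes summed to 102% to 104% of the totals, so some reads had been counted for more than 1 gene. The median implied read number per table entry was 1177 and 1306 in untreated and CSE-treated HPNE and 1318 and 1292 in Capan1, and the 10 genes with most reads took 6.84%, 6.21%, 3.65% and 3.70% of the totals. The lowest maximum of any gene was 5.00 RPKM in both of the deposited tables, but none of the 13 mitochondrially encoded genes was listed in either line and no entry lay on the mitochondrial genome, so absence does not establish a level and a missing gene is described as not listed. The deposited log2 fold change differed from the log2 ratio of the RPKM values by a median of -0.08 in HPNE and 0.03 in Capan1. The score the authors deposited as a direction flag marked log2 fold changes beyond 1. Counted over all entries, before those that share a symbol were merged, it marked 88 higher and 212 lower in HPNE and 92 higher and 86 lower in Capan1. The tables hold no p-value per gene. The deposited tables of enriched terms give gene counts, fold enrichment (a ratio) and Benjamini-adjusted p-values, which are quoted as the authors' values. Their terms are Gene Ontology processes for HPNE and KEGG pathways for Capan1.

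The design had been written for values of several kinds, and with RPKM the comparison was log2((CSE + 1)/(untreated + 1)), a pseudocount of 1 RPKM. This scale understates ratios of genes with low values. Of entries that shared a symbol the one with the highest mean was kept, which turned 9059 entries into 9015 symbols in HPNE and 9802 into 9760 in Capan1. A gene counted as different when it had at least 5 RPKM in one or both libraries and a ratio of at least 2 on that scale. No test was run, since 1 library per group gives no spread between replicates. The 95% intervals on single ratios are exact conditional binomial (Clopper-Pearson) intervals on the implied reads and assume independent reads. Overlaps between the lines were set against the product of the list sizes divided by the number of genes listed in both tables.

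The 42 gene groups were fixed before the data were examined, as were the groups of libraries, the threshold, the rule for named genes and most of the alternatives. For groups with at least 3 listed members, the median log2 ratio was placed among 10000 random lists of equal size drawn from 20 bins of mean expression. A median below percentile 2.5 or above percentile 97.5 was called outside. Groups listed with fewer members are described by values alone. The rule for named genes took, per line, the 10 largest differences in each direction, up to 4 members past 2-fold of each group (2 most abundant members where none passed), 15 genes chosen for the study's question (PAF1, CHRNA7, FOSL1, CYP1A1, CYP1B1, NQO1, HMOX1, CD44, PROM1, ALDH1A1, ALDH1A3, SOX9, KLF4, MYC and NES), and the genes past 2-fold in both lines. The report names part of these. Line and cell type markers are given as values of the line identity check, and PDGFRA was chosen after its values were seen.

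Alternatives were pseudocounts of 0.1 and 5, filters of 1, 5 and 10 RPKM, centring on the median of all genes, rescaling without the 1% most abundant genes, the deposited log2 fold change, thresholds of 1.5-fold and 4-fold, unmatched random lists and the mean in place of the median. After the data were seen, removal of a trend by gene length and GC content (running medians over 40 bins) and removal of small RNA genes were added. GC content was taken from GENCODE release 29 transcripts by symbol, older symbol or unique RefSeq synonym, which gave a value for 98.2% of HPNE and 98.1% of Capan1 genes. The synonyms were added after results had been seen, since without them 95.3% and 95.1% of genes had a value and 4 of the 24 oxidative phosphorylation genes were dropped with the trend removed. The remaining 20 lay inside the random lists in both lines even before trend removal (percentiles 96.8 and 6.05), and after it 1 of the 4 medians of ribosomal protein and oxidative phosphorylation genes lay outside in place of 2. That annotation was used for GC content alone, and all coordinates are the authors' deposited hg19 positions.

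The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data. Reads for both libraries of a line were drawn from its untreated RPKM values at a fixed depth, with counting error alone. The 2-fold criterion called 97 of 97 genes given a 3-fold difference and 0 of 100 given a 1.5-fold difference in the HPNE simulation of 8663 genes, and 97 of 98 and 1 of 100 in the Capan1 simulation of 9537 genes. It called 4 of 8466 unchanged genes in the HPNE simulation and 4 of 9339 in that for Capan1. The simulation held no variation between cultures and no length trend, so these are not false-call rates for the real libraries. Reads shared by paralogs (AKR1C, SAA, HSPA1 and metallothionein genes) and by overlapping genes (MMP1 with WTAPP1) could not be separated. Small RNA genes were left out of the named genes, since their precursors overlap host genes.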

Results

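RNA of 2 human pancreatic cell lines was sequenced with and without long exposure to cigarette smoke extract (CSE). HPNE is an immortalized line derived from nestin-positive cells of normal pancreatic ducts, and Capan1 is a pancreatic adenocarcinoma line with a KRAS mutation, established from a liver metastasis. CSE was made by drawing the smoke of research cigarettes through culture medium, and the treated cells were kept in 1% CSE for 80 days over 40 passages. The design held 4 groups, untreated and CSE-treated cultures of each line, with 1 library per group. The deposited values implied 24132320 reads in the untreated HPNE library, 25206185 in the HPNE CSE library, 24651975 in the untreated Capan1 library and 24244932 in the Capan1 CSE library. Expression was given in RPKM, a read count scaled to transcript length and library total, and every listed gene had at least 5 RPKM in one or both libraries of its line, with 9015 gene symbols listed in HPNE and 9760 in Capan1. Each gene was compared as log2((CSE + 1)/(untreated + 1)) of its RPKM values, and fold values given for single genes are plain RPKM ratios. Their 95% intervals are exact binomial intervals on the implied reads, which cover counting error only. With 1 library per group no difference has a replicate check, so the values describe these 4 cultures. Coordinates are on hg19.

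The marker genes of the lines separated the libraries as labelled. The epithelial genes EPCAM and CDH1 (E-cadherin) stood at 81.5 and 54.6 RPKM in untreated Capan1 and at 65.3 and 60.4 RPKM in the Capan1 CSE library, and neither was listed in HPNE. The intermediate filament gene VIM (vimentin) stood at 2072 and 1631 RPKM in untreated and CSE-treated HPNE, against 10.4 and 9.72 RPKM in Capan1. The matrix gene SPARC was listed at 1012 and 545 RPKM in HPNE and was not listed in Capan1. NES (nestin) was listed in both lines, at 31.3 and 43.6 RPKM in HPNE and at 5.86 and 6.90 RPKM in Capan1. All 9 fibroblast markers were listed in HPNE and none in Capan1, with COL1A1 at 376 and DCN at 151 RPKM in untreated HPNE, whereas 2 of 12 pancreatic ductal genes were listed in HPNE and 5 in Capan1. None of the 9 endothelial markers was listed in either line. Of 10 leukocyte markers, CD68 was listed in both lines and CD14 in HPNE, where it was 12.05 RPKM in the untreated and 4.28 RPKM in the CSE library.

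The first comparison asked which transcripts differ in the non-tumour line after 80 days in CSE. The CSE library of HPNE held more transcript of detoxification and stress genes and less transcript of collagens and other matrix genes. SERPINB2, a plasminogen activator inhibitor (chromosome 18, 61554939 to 61571124), was 16.3-fold higher with CSE (95% interval 14.6 to 18.2), at 6.78 RPKM untreated and 110.4 RPKM treated. The interstitial collagenase MMP1 (chromosome 11, 102660641 to 102668966) was 8.07-fold higher (7.50 to 8.69), and the pseudogene WTAPP1, which overlaps it, was 1.17 RPKM untreated and 7.68 RPKM with CSE. ALDH1A3, a retinaldehyde dehydrogenase gene (chromosome 15, 101419897 to 101456830), was 6.23-fold higher (5.74 to 6.76). In the other direction, TGFB3, a TGF-beta ligand (chromosome 14, 76424440 to 76448365), was 7.58-fold lower (6.77 to 8.50) and the fibrillar collagen COL3A1 (chromosome 2, 189839099 to 189877472) was 3.67-fold lower (3.61 to 3.73). In total, 212 of 9015 genes (2.35%) differed at least 2-fold, 85 of them higher and 127 lower with CSE, while 7993 (88.7%) lay within 1.5-fold. The median log2 ratio of all HPNE genes was 0.10, and groups are therefore described relative to that median. Centring on it gave 62 genes higher and 163 lower, so that the share of higher genes was 27.6% in place of 40.1%. A threshold of 1.5-fold, applied to uncentred ratios, gave 565 higher and 457 lower (55.3% higher). Those ratios had 5th and 95th percentiles of -0.59 and 0.62 around the median of 0.10. The uncentred count favours higher genes, so it does not show that smaller differences lean upward.

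Xenobiotic and antioxidant genes stood highest among the HPNE groups. Of 28 NRF2 antioxidant and detoxification genes 27 were listed, 25 lay above the all-gene median and 10 were at least 2-fold higher, with none 2-fold lower. GCLC and GCLM, the subunits of the enzyme that starts glutathione synthesis, were 3.67-fold (3.49 to 3.86) and 2.78-fold (2.65 to 2.92) higher. The heme oxygenase gene HMOX1 was 3.30-fold higher (3.10 to 3.51), and the quinone reductase gene NQO1 went from 534 to 1223 RPKM. The aldo-keto reductase genes AKR1C1, AKR1C2 and AKR1C3 were 4.37-fold, 4.25-fold and 3.86-fold higher, although these near-identical paralogs can exchange reads. Of 12 aryl hydrocarbon receptor targets 7 were listed, and 4 of them were 2-fold higher, CYP1A1, TIPARP, NQO1 and IL1B. Of these, NQO1 is also in the NRF2 group and IL1B in the cytokine group. CYP1A1, the smoke-inducible cytochrome P450 (chromosome 15, 75011883 to 75017877), was 4.83-fold higher (3.70 to 6.36) but reached only 5.11 RPKM, and TIPARP was 3.67-fold higher (3.44 to 3.93). CYP1B1 differed less, at 99.4 RPKM untreated and 127 RPKM with CSE.

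All 12 heat shock genes lay above the all-gene median in HPNE and 4 were 2-fold higher. Among these, the chaperone gene HSP90AA1 was 2.47-fold higher (2.43 to 2.51) and the co-chaperone gene HSPH1 was 2.47-fold higher (2.34 to 2.61). HSPA1A and HSPA1B, which share most of their sequence, were 101 and 97.0 RPKM untreated and 215 and 204 RPKM with CSE. The group medians on the log2 scale were 1.04 for aryl hydrocarbon receptor targets (the value of IL1B), 0.78 for NRF2 genes and 0.66 for heat shock genes. Each lay at percentile 100 of 10000 random lists of the same size matched on mean expression, which describes these libraries and is not a test of the treatment. Nuclear oxidative phosphorylation genes had 20 of 24 members above the all-gene median (median log2 0.26, percentile 97.7), and all 3 listed histone genes of 13 were above it (median 0.60, percentile 99.2). Neither group had a member past 2-fold. Short transcripts were higher than long ones in the HPNE CSE library, with medians of 0.22 and -0.03 in the shortest and longest eighth of genes. With the trend by length and GC content removed, a setting added after seeing the data, the oxidative phosphorylation genes had a median of 0.15 inside the random lists (percentile 88.8).

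Matrix and fibroblast genes stood lowest among the HPNE groups. Of 27 collagen and extracellular matrix genes 24 were listed, 22 lay below the all-gene median and 9 were at least 2-fold lower, with none 2-fold higher (median log2 -0.80, percentile 0). COL5A1 was 3.50-fold lower (3.41 to 3.60), the collagen cross-linking enzyme LOX was 2.92-fold lower (2.79 to 3.05) and the microfibril gene FBN2 was 2.78-fold lower (2.64 to 2.93). COL1A1 and COL1A2, which encode the chains of type I collagen, went from 376 to 180.0 RPKM and from 226 to 92.2 RPKM. The authors' deposited table of terms for genes lower in HPNE gives extracellular matrix organization 14 genes and a fold enrichment of 14.0, and collagen fibril organization 9 genes and a fold enrichment of 32.3. All 9 fibroblast markers lay below the all-gene median (median -0.81, percentile 0.01), although 5 of them are also matrix genes, and PDGFRA differed little, at 60.1 RPKM untreated and 55.5 RPKM with CSE. Mesenchymal genes were lower as a group, with 10 of 12 listed members below the all-gene median (median -0.28, percentile 0.33), and the actin-binding gene TAGLN was 2.18-fold lower (2.02 to 2.35).

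**Figure D1:**
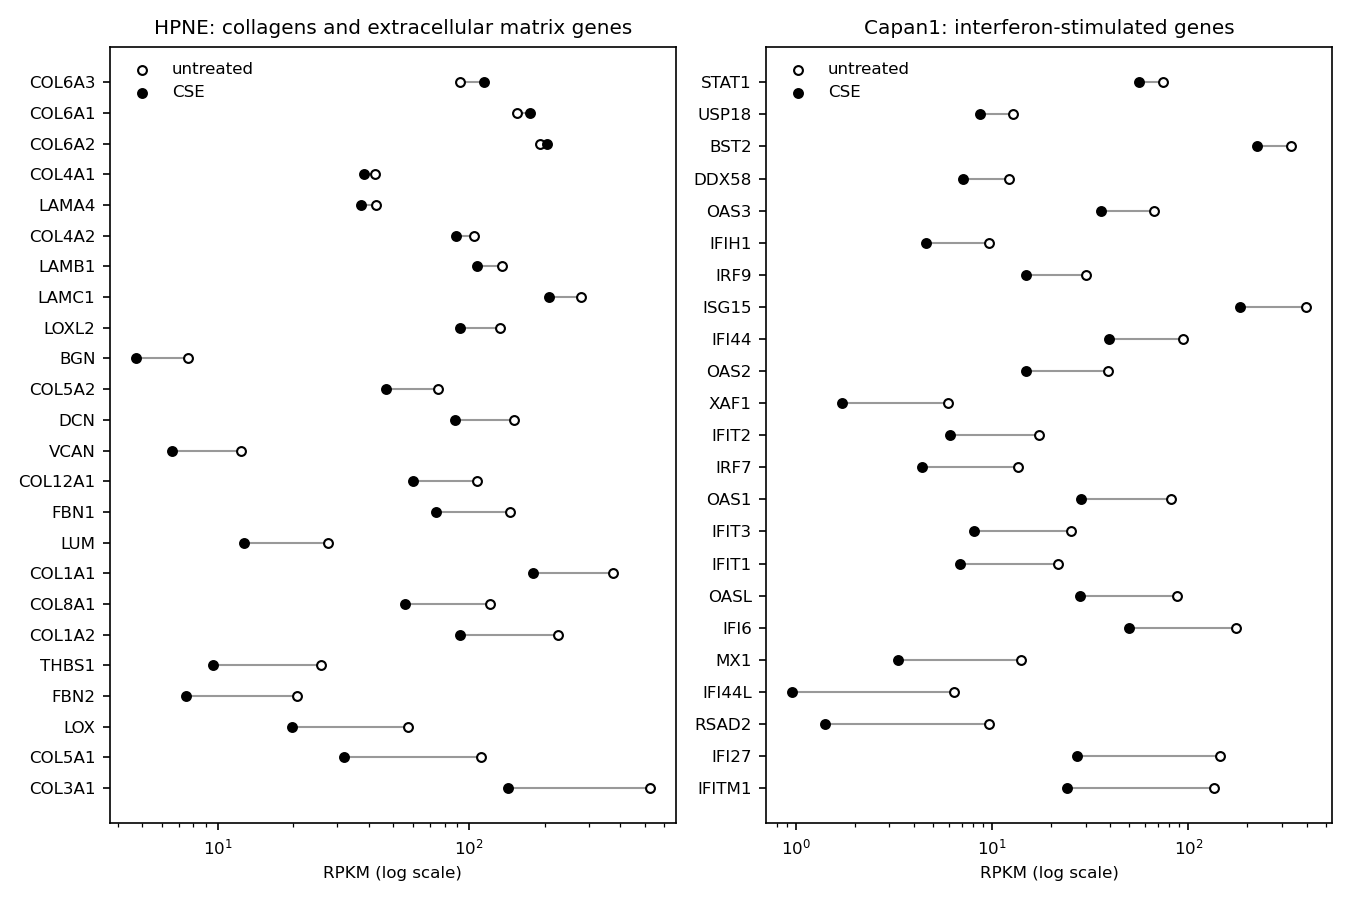
RPKM on a log axis in the untreated (open) and CSE (filled) library for each listed gene of 2 groups, matrix genes in HPNE on the left and interferon-stimulated genes in Capan1 on the right. Of the 24 matrix genes, the COL6A chains alone had a higher RPKM in the CSE library, and all 23 interferon-stimulated genes had a lower one.

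Signalling and inflammatory genes of HPNE went both ways. TGFB2 was 4.19-fold lower (4.05 to 4.35), and of 14 TGF-beta targets 8 were listed, 5 of them below the all-gene median (median -0.23, percentile 1.21). The mean of these targets, -0.12, lay inside the random lists. CTGF, a matricellular protein gene, went from 2096 to 1028 RPKM, whereas the activin subunit gene INHBA was 2.36-fold higher (2.10 to 2.66). SERPINE1, another listed target, went from 1190 to 1976 RPKM. Of 23 cytokine and chemokine genes 13 were listed, 10 of them below the all-gene median (median -0.12, percentile 2.82, inside the random lists). IL1B (702 to 1444 RPKM) and LIF (12.02 to 29.98 RPKM) were 2-fold higher, and the group lay outside the random lists under 3 of 12 alternatives. The acute-phase gene SAA1 was 7.19-fold lower (6.58 to 7.87), with its paralog SAA2 at 57.6 and 8.36 RPKM, and the inflammasome cytokine gene IL18 was 6.09-fold lower (5.01 to 7.52). Antigen presentation genes had 10 of 12 listed members below the all-gene median (median -0.28, percentile 0.13), among them B2M, the light chain of class I molecules, at 984 and 767 RPKM. Hypoxia and glycolysis genes had 18 of 23 below it (median -0.09, percentile 1.80), and with the length and GC trend removed the median was still -0.09 while the percentile was 2.76, just inside the random lists. In this group the glucose transporter gene SLC2A3 was 2.05-fold lower (1.97 to 2.13). The metallothionein gene MT1B had 262 implied reads untreated and 2 with CSE, a 137-fold difference with an interval of 37.5 to 1136, but it shares sequence with other metallothioneins, whose listed members had a median of 0.13 (percentile 63.6).

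Stem cell markers were set apart because the series title names the pancreatic cancer stem cell population. In HPNE, 9 of 24 stem cell and pluripotency markers were listed and their median of 0.06 lay inside the random lists (percentile 34.7). ALDH1A3 was 6.23-fold higher whereas ALDH1A1 was 2.98-fold lower (2.53 to 3.51), and the aldehyde dehydrogenase family had 8 of 11 listed members below the all-gene median (median -0.18, percentile 0.97), though its mean was 0.05 because of ALDH1A3. CD44, a hyaluronan receptor used to sort such cells, was 68.2 RPKM untreated and 70.9 RPKM with CSE, and the pluripotency factor KLF4 was 3.40 and 6.496 RPKM. PAF1, a subunit of the transcription elongation complex of the same name, was 17.0 and 17.7 RPKM, a ratio of 1.04 (0.951 to 1.13), and the 6 members of that complex had a median of 0.20 (percentile 79.2). PROM1 and the nicotinic receptor gene CHRNA7 were not listed in either line. Of 15 nicotinic receptor subunits, CHRNB1 was listed in both lines, at 5.36 and 4.12 RPKM in HPNE and 5.88 and 5.01 RPKM in Capan1.

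The second comparison asked the same of the adenocarcinoma line. In Capan1 the CSE library had more transcript of aryl hydrocarbon receptor targets, cytokines and EGF receptor ligands and less of interferon-stimulated genes. CYP1A1 was 63.7-fold higher with CSE (50.7 to 81.6), at 1.13 RPKM untreated and 72.3 RPKM treated, and CYP1B1 (chromosome 2, 38294746 to 38303323) was 9.91-fold higher (9.19 to 10.7). SERPINB2 was 5.84-fold higher (5.56 to 6.14), ALDH1A3 5.11-fold higher (4.98 to 5.25) and the neutrophil chemokine gene CXCL8 5.53-fold higher (4.82 to 6.39). The interferon-induced membrane protein gene IFITM1 (chromosome 11, 313991 to 315272) was 5.64-fold lower (5.08 to 6.26), and the T cell chemokine gene CCL5 was 6.44-fold lower (4.99 to 8.43). In total, 141 of 9760 genes (1.44%) differed at least 2-fold, 71 higher and 70 lower with CSE, and 9268 (94.96%) lay within 1.5-fold around an all-gene median of -0.03.

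Interferon-stimulated genes were the lowest group in Capan1. Of 25 genes 23 were listed, all 23 lay below the all-gene median and 16 were at least 2-fold lower (median log2 -1.36, percentile 0). IFI27 was 5.37-fold lower (4.89 to 5.89), RSAD2, an antiviral enzyme, 6.89-fold lower (5.68 to 8.41) and the antiviral GTPase gene MX1 4.24-fold lower (3.73 to 4.82). IFI6 went from 175 to 49.99 RPKM. Outside that list, the death ligand gene TNFSF10 was 3.73-fold lower (3.44 to 4.04). In HPNE, 9 genes of the list were listed and their median of -0.09 lay inside the random lists (percentile 6.31), with IFITM1 at 209 and 108 RPKM. The authors' deposited table of pathway terms for genes lower in Capan1 lists the RIG-I-like receptor pathway with 3 genes, IFIH1, ISG15 and IRF7, and a Benjamini-adjusted p of 0.476. Antigen presentation genes had 11 of 12 listed members below the all-gene median (median -0.43, percentile 0), with B2M 1.62-fold lower (1.59 to 1.64).

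EGF receptor ligand and ERK pathway output genes were higher in the Capan1 CSE library. Of 11 EGF receptor family and ligand genes 9 were listed, and 3 ligands were 2-fold higher, EREG at 2.79-fold (2.67 to 2.92), HBEGF at 2.77-fold (2.64 to 2.90) and TGFA at 2.47-fold (2.36 to 2.57), for a group median of 0.86 (percentile 100). All 12 listed ERK pathway output genes lay above the all-gene median (median 0.50, percentile 100), among them the ERK phosphatase gene DUSP6 at 2.28-fold (2.17 to 2.39) and IER3 at 2.36-fold (2.27 to 2.46). FOSL1, an AP-1 subunit gene, was 3.69-fold higher (3.42 to 3.98) and EGR1 was 2.69-fold higher (2.28 to 3.18), but the 10 listed AP-1 and immediate early genes together had a median of 0.09 inside the random lists (percentile 93.6). Cytokines and chemokines had 4 of 11 listed members 2-fold higher and 1 lower (median 0.71, percentile 100). IL1B was 3.24-fold higher (3.12 to 3.37) and LIF went from 8.20 to 21.8 RPKM. The neurotrophic factor gene ARTN was 4.12-fold higher (3.70 to 4.61).

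Detoxification genes were also higher in the Capan1 CSE library. Of 26 listed NRF2 genes 24 lay above the all-gene median and 2 were 2-fold higher, GCLM at 2.08-fold (1.99 to 2.19) and the efflux transporter gene ABCC3 at 2.17-fold (2.06 to 2.27), for a median of 0.51 (percentile 100). NQO1 was 155 RPKM untreated and 225 RPKM with CSE, a ratio of 1.45 (1.41 to 1.49). GCLC, the partner subunit gene of GCLM, went the other way than in HPNE, from 47.8 to 34.7 RPKM, and HMOX1 was not listed in Capan1. The 9 listed aryl hydrocarbon receptor targets had a median of 0.59 (percentile 100). The 4 that were 2-fold higher were CYP1A1, CYP1B1, IL1B and TIPARP, the last at 2.40-fold (2.30 to 2.49). Heat shock genes had a median of -0.07 in Capan1 (percentile 46.1), with HSPA8 at 1098 and 1040 RPKM. The difference between the lines was not tested for any of these groups.

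Of 24 stem cell markers 14 were listed in Capan1, 11 of them above the all-gene median (median 0.21, percentile 99.9), and 2 were 2-fold higher. These were ALDH1A3 and the drug efflux transporter gene ABCG2, which was 3.37-fold higher (2.85 to 3.98) at 1.59 and 5.34 RPKM. CD44 went from 60.1 to 70.6 RPKM, SOX9, a duct and progenitor transcription factor gene, from 5.37 to 6.72 RPKM, KLF4 from 20.7 to 21.4 RPKM and MYC from 77.5 to 71.2 RPKM. PAF1 had a ratio of 1.13 (1.04 to 1.22), at 19.7 and 22.2 RPKM, and the 6 members of its complex had a median of -0.09 (percentile 21.5). The 4 listed Wnt pathway genes also lay above the random lists (median 0.35, percentile 99.6), among them the cyclin gene CCND1 at 89.7 and 114 RPKM. So did p53 targets (percentile 99.03), matrix proteases (percentile 99.4) and TGF-beta targets (percentile 98.5), but with the length and GC trend removed these lay inside, at percentiles 95.3, 97.48 and 96.8.

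Mucin, lipid synthesis and histone genes had group medians below the random lists in Capan1. Of 17 mucin and gastrointestinal secretory genes 8 were listed, 5 of them below the all-gene median and 3 above it, and 2 were 2-fold lower (median -0.53, percentile 0), the membrane mucin genes MUC4 at 3.24-fold (3.11 to 3.37) and MUC1 at 2.48-fold (2.23 to 2.75). The 3 above it were MUC20 and the adhesion genes CEACAM5, at 53.8 and 72.4 RPKM, and CEACAM6, at 200 and 267 RPKM. Cholesterol synthesis and uptake genes had 17 of 20 members below the all-gene median (median -0.31, percentile 0) and fatty acid synthesis genes 8 of 10 (median -0.29, percentile 0.06), with the desaturase gene SCD 1.47-fold lower (1.44 to 1.496). All 9 listed replication-dependent histone genes lay below it and 3 were 2-fold lower (median -0.53, percentile 0), among them HIST1H1D at 8.75 and 3.07 RPKM and HIST1H3B at 8.77 and 3.66 RPKM. These 3 rested on few reads, 102 to 168 implied reads untreated and 42 to 72 with CSE. The authors' deposited table of pathway terms for genes lower in Capan1 lists systemic lupus erythematosus, a term that holds histone genes, with a fold enrichment of 10.3. All 27 ribosomal protein genes (median -0.22, percentile 0.24) and 21 of 24 oxidative phosphorylation genes (median -0.18, percentile 0.82) lay below the all-gene median, with none past 2-fold. Short transcripts were lower than long ones in this CSE library, with medians of -0.11 and 0.03 in the shortest and longest eighth of genes. With that trend removed both groups still lay outside the random lists, ribosomal protein genes with a median of -0.15 and oxidative phosphorylation genes with one of -0.13. The call for the latter rests on gene synonyms that were added to find GC content after results had been seen: the 20 genes found without them lay inside the random lists before (percentile 6.05) and after trend removal (percentile 11.5).

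**Figure D2:**
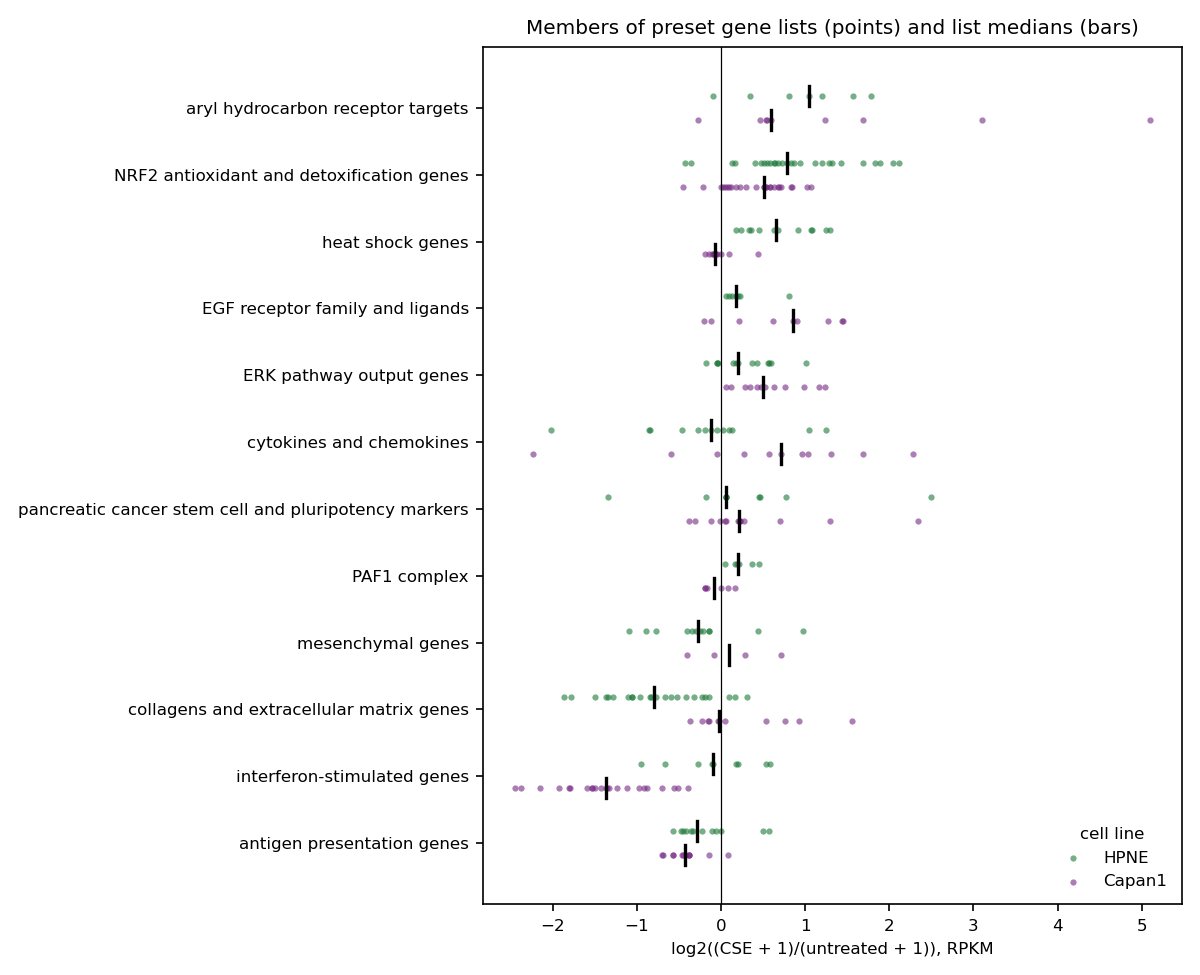
Log2 ratio of CSE over untreated on the RPKM + 1 scale for each listed member (points) of 12 gene groups in HPNE (green) and Capan1 (purple), with the group median as a bar. Interferon-stimulated genes in Capan1 (median -1.36) and matrix genes in HPNE (median -0.80) lie farthest below 0, and aryl hydrocarbon receptor targets have medians above 0 in both lines.

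Of the 42 groups, 34 had at least 3 listed members in each line. In HPNE 13 of them, and in Capan1 19, had medians outside the central 95% of random lists, where lists of genes drawn independently would put 1.7. Members of a group can vary together and the groups share genes, so these counts are no test against chance. DNA repair genes lay inside in both lines, at percentiles 29.6 in HPNE and 92.4 in Capan1. Mitotic and G2/M genes also lay inside, with medians of 0.26 in HPNE (percentile 97.3) and -0.08 in Capan1 (percentile 12.6), but their calls changed with the setting. They lay outside in HPNE under 4 of 12 alternatives (up to percentile 98.6), and in Capan1 with the length and GC trend removed (percentile 2.17). The unfolded protein response group also stayed inside, at percentile 70.2 in HPNE, where the asparagine synthetase gene ASNS was 2.32-fold higher (2.10 to 2.57), and at percentile 16.7 in Capan1. Epithelial adhesion and keratin genes lay at percentile 15.8 in HPNE, with 5 of 20 listed, and at percentile 53.2 in Capan1, where KRT19 was 731 and 739 RPKM.

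The last comparison asked which differences the normal and the tumour line had in common. SERPINB2, ALDH1A3, CYP1A1, FOSL1, GPAT3, IL1B, TIPARP, LIF, AKAP12, LPXN and GCLM were at least 2-fold higher with CSE in both lines. These 11 genes came from 57 higher genes in HPNE and 38 in Capan1 among the 7894 genes listed for both, where independent lists would share 0.274 genes. With a pseudocount of 5 the shared genes were 6, as CYP1A1, GPAT3 and LPXN in HPNE and AKAP12, GCLM and LPXN in Capan1 no longer reached 2-fold. No gene was 2-fold lower in both lines, from 55 and 21 genes, where independent lists would share 0.146. The scaffold gene AKAP12 was 4.29-fold higher in Capan1 (3.78 to 4.89), from 1.37 RPKM, and 2.20-fold higher in HPNE (2.15 to 2.25), from 47.3 RPKM. GPAT3, a glycerol-3-phosphate acyltransferase gene, was 3.94-fold (3.54 to 4.41) and 2.56-fold (2.31 to 2.85) higher in Capan1 and HPNE. FOSL1 was 2.65-fold higher in HPNE (2.52 to 2.79), where its level went from 51.3 to 136 RPKM.

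THBS1 and DUOX2 passed 2-fold in opposite directions. The thrombospondin gene THBS1 was 2.70-fold lower in HPNE (2.55 to 2.85) and 3.07-fold higher in Capan1 (2.94 to 3.20). The dual oxidase gene DUOX2 was 3.59-fold higher in HPNE (3.09 to 4.17) and 3.44-fold lower in Capan1 (2.97 to 3.998). Its levels were 1.45 and 5.19 RPKM in HPNE and 5.21 and 1.51 RPKM in Capan1, near the lowest listed values, and with a pseudocount of 5 its log2 ratios of 0.66 and -0.65 did not reach 2-fold. Its maturation factor gene DUOXA2 was 5.20-fold higher in HPNE (3.88 to 7.08). Of the 57 genes higher in HPNE and also listed in Capan1, 45 lay above the Capan1 all-gene median, and of the 38 genes higher in Capan1, 30 lay above the HPNE median. Of the lower genes listed in both tables, 35 of 55 from HPNE lay below the Capan1 median and 13 of 21 from Capan1 lay below the HPNE median. Across all 7894 genes the log2 ratios of the lines had a Pearson correlation of 0.180 and a Spearman correlation of 0.0986, and genes are not independent replicates.

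**Figure D3:**
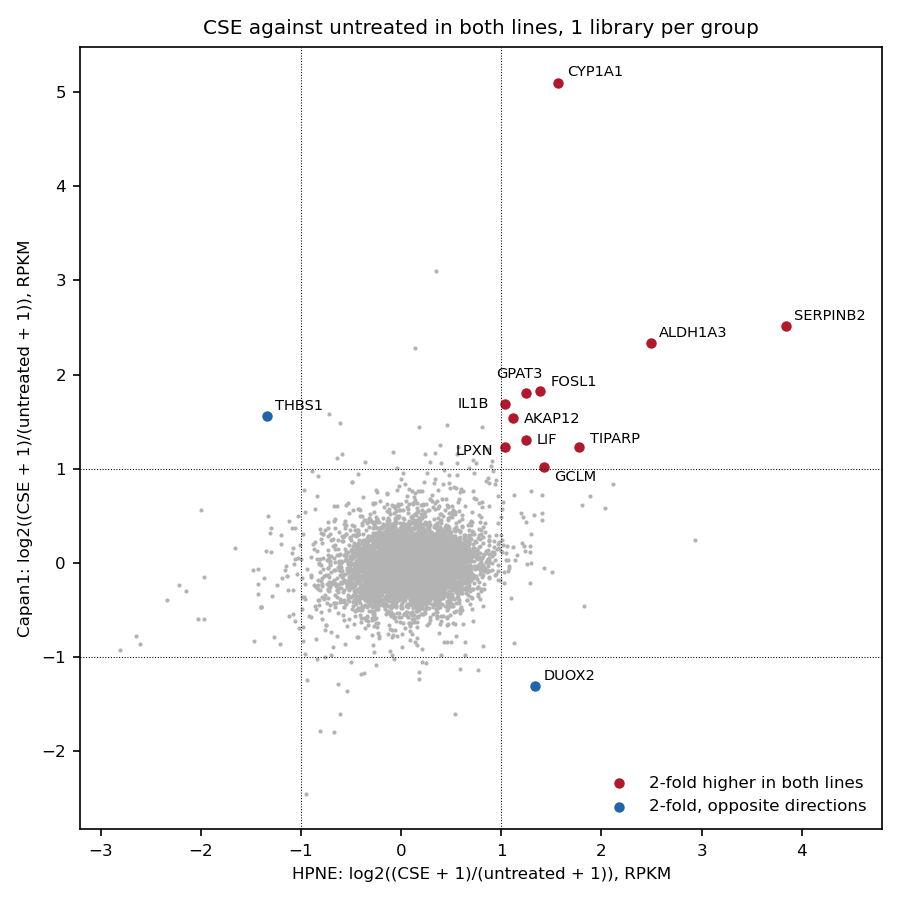
Log2 ratio of CSE over untreated in HPNE (horizontal) and Capan1 (vertical) for the 7894 genes listed in both lines, 1 point per gene, with dotted lines at 2-fold. The 11 red genes are 2-fold higher in both lines, the 2 blue genes pass 2-fold in opposite directions, and no gene lies past 2-fold at the lower left.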

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

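The tests of library scaling, of other differences between the cultures, of the share of mesenchymal cells, of TGF-beta signalling and of the trend as the whole cause in Capan1 ribosomal protein genes were chosen after the results were seen, and removal of the length and GC trend was a setting added after seeing the data. The synonyms used to find GC content were also added after the results were seen, and without them 1 in place of 2 of the 4 medians in the last pattern lay outside after trend removal, with oxidative phosphorylation genes in Capan1 at percentile 11.5. None of the differences between the lines given here was tested, since each line has 1 library per treatment.

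THBS1 and DUOX2 passed 2-fold in opposite directions in the lines. The log2 ratio of CSE over untreated in HPNE minus that in Capan1 was -2.90 for THBS1 (-1.34 in HPNE and 1.56 in Capan1), and the difference was not tested. For DUOX2 it was 2.64 (1.34 in HPNE and -1.30 in Capan1), also not tested. Gene groups whose medians lay outside the random lists on opposite sides were oxidative phosphorylation genes, with 0.44 as the HPNE median minus the Capan1 median (0.26 and -0.18), histone genes with 1.13 (0.60 and -0.53, from 3 and 9 listed genes) and TGF-beta targets with -0.39 (-0.23 and 0.16). The TGF-beta call was lost in HPNE with the mean in place of the median (percentile 9.69) and in Capan1 under 4 of 12 alternatives, and the oxidative phosphorylation call was lost in HPNE with the length and GC trend removed. These differences were not tested either.

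Interferon-stimulated genes were lower in the Capan1 CSE library, all 23 listed ones, with a median log2 ratio of -1.36. Scaling between the libraries would need a shift of all genes by about that amount, and the median of all Capan1 genes was -0.0257. A trend by gene length or GC content is also argued against, since the group median after its removal was -1.35, at percentile 0 of the random lists. What stays open is what set the cultures apart: with 1 library per group, the CSE treatment and other differences between the 2 cultures cannot be told apart, among them their time in culture, density or medium. Lower interferon signalling after long exposure to CSE may be one explanation, as a hypothesis that further cultures would have to test.

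Collagen and matrix genes were lower in the HPNE CSE library, with a median of -0.80. The length and GC trend is argued against as the whole cause, since a median of -0.60 remained after its removal, at percentile 0. A lower share of mesenchymal cells stays open. No mesenchymal gene is on the matrix list, so the 12 listed ones are the genes given above. SPARC and the fibronectin gene FN1 (log2 ratio -0.77) among them are themselves matrix genes, so the 2 groups are not fully separate. Of the 12, 2 (TAGLN and SPARC) were at or below the matrix median, but the lower quartile of the 12 was -0.50, above it. The shifts were uneven: 10 of the 12 lay below 0, with VIM 1.27-fold and THY1 1.23-fold lower. The other 2 lay above 0, and 1 of these, SNAI2, was 2.03-fold higher by plain RPKM ratio. An equal fall of all these genes, as from a lower share alone, is not what the values show. The 4 fibroblast markers that are not on the matrix list had a median of -0.60 and ranged from -0.81 for FAP to -0.11 for PDGFRA. Lower TGF-beta signalling stays open and may contribute. No TGF-beta target is on the matrix list, so the 8 listed ones are the genes given above. Their median was -0.23, at percentile 1.25 here and 1.21 above, and TGFB2 and TGFB3 were lower. In the other direction, INHBA and SERPINE1 were higher, 3 of the 8 targets lay above 0, and the mean of the targets lay inside the random lists. The treatment itself and time in culture, which the single libraries do not separate, were not tested.

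Oxidative phosphorylation genes leaned upward in HPNE and downward in Capan1, and ribosomal protein genes lay below the random lists in Capan1, so that 3 of the 4 group medians lay outside. A gene length or GC trend may account for part of this: across genes, length and log2 ratio had rank correlations of -0.229 in HPNE and 0.187 in Capan1, and after removal of the trend 2 of the 4 medians lay outside. In HPNE the oxidative phosphorylation median went from 0.26 to 0.15 (percentile 88.8) and the ribosomal protein median from 0.17 to 0.01. In Capan1 the ribosomal protein median went from -0.22 to -0.15 (percentile 0.855) and the oxidative phosphorylation median from -0.18 to -0.13 (percentile 1.86), which argues against the trend as the whole cause in the Capan1 ribosomal protein genes. What else set them apart stays open, and no biological explanation was tested.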

How the results depend on the processing

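Removal of the length and GC trend and of small RNA genes was chosen after seeing the data, and the other alternatives were set before. In the main setting 212 genes differed 2-fold in HPNE, 141 in Capan1 and 11 were shared. A pseudocount of 5 gave 100 in HPNE (38 higher, 62 lower), 66 in Capan1 (36 higher, 30 lower) and 6 shared, since it shrinks ratios of low genes. Requiring 5 RPKM in both libraries gave 135 in HPNE, 71 of them lower, and 86 in Capan1 (47 higher, 39 lower), since it removes genes low in one library. The deposited log2 fold change gave 204 lower genes in HPNE, counted by symbol, and the cause was not tested. A threshold of 1.5-fold on uncentred ratios gave 1022 in HPNE (565 higher, 457 lower), 492 in Capan1 (239 higher, 253 lower) and 75 shared. One of 4-fold gave 16 (7 higher, 9 lower), 10 (5 higher, 5 lower) and 2 shared. The correlation between the lines was 0.0986 by rank, against 0.180, and the cause was not tested. With the trend removed it was 0.2499, and the trends with length that were removed had opposite signs in the lines (rank correlations of -0.229 and 0.187). In the other 94 comparisons counts stayed within 1.5 times, and the correlation moved by less than its spread over 200 Poisson resamples.

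Group medians kept direction and side of the threshold in 782 comparisons with the main setting. They came inside the random lists in 11 and went outside in 20, and 1 changed sign: aldehyde dehydrogenases in HPNE had a mean of 0.046 against a negative median, because of ALDH1A3. Outside groups numbered 13 to 15 in HPNE and 17 to 20 in Capan1. Of the values of named genes, 1442 stayed inside their counting interval, 397 moved and none of those past 2-fold changed sign. Filters of 0 and 1 RPKM equalled the main setting because the tables start at 5 RPKM, so they tested nothing. Centring shifts a group and its random lists by the same amount, so it could not move a group across the threshold. The 782 agreeing comparisons and the numbers of alternatives given for single groups include such settings, so they overstate how much was tested. The authors' p-values as a criterion gave no value, since the tables hold no p-values per gene. Scaling factors from counts also gave none, since the tables hold no counts and the implied reads were not used for this. No paired analysis was possible within a line because each group has 1 library, and a fit of treatment with line as a block, which would leave 1 residual degree of freedom, was not run. Depth limits genes near 5 RPKM: CYP1A1 in HPNE rested on 67 and 337 implied reads.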

Other observations

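The genes in this paragraph and the next were chosen after their values were seen. In Capan1, the prostaglandin synthase gene PTGS2 was 25.2 RPKM untreated and 77.8 RPKM with CSE. The cornified envelope genes SPRR1A and SPRR1B were 9.69 and 42.1 RPKM untreated and 28.3 and 137 RPKM with CSE. TXNIP, which encodes a thioredoxin inhibitor, was 370 RPKM untreated and 151 RPKM with CSE. The interferon-inducible genes IFITM3 and DDX60, which are not in the preset group, were 242 and 45.8 RPKM untreated and 78.9 and 12.6 RPKM with CSE.

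In HPNE, the collagen genes COL11A1 and COL15A1, which are not in the preset group, were 78.6 and 65.6 RPKM untreated and 20.05 and 19.5 RPKM with CSE. The carboxypeptidase gene CPA4 was 312 RPKM untreated and 82.7 RPKM with CSE, and the growth arrest gene GAS1 was 16.2 and 3.77 RPKM. The forkhead gene FOXL1 and the annexin gene ANXA10 were higher, at 20.5 and 63.2 RPKM and at 54.6 and 146 RPKM.

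Of the 175 small RNA genes listed in HPNE and 194 in Capan1, those that are not microRNA genes took opposite sides in the lines. In HPNE, 55 of 83 lay above the all-gene median with a median log2 ratio of 0.30, and in Capan1 30 of 85 did, with a median of -0.17. The shortest eighth of all genes leaned the same way in each line (medians 0.22 and -0.11). Whether the length trend accounts for the small RNA genes was not tested.

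The authors' deposited table of terms for genes higher in HPNE lists response to xenobiotic stimulus with 4 genes and a fold enrichment of 41.3, and response to oxidative stress with 7 genes and a fold enrichment of 10.1. The authors' deposited table of terms for genes lower in HPNE lists TGF-beta receptor signaling with 8 genes, among them TGFB2, TGFB3, TGFBR1 and TGFBR2, and a fold enrichment of 13.9. In the authors' deposited table of pathways for genes higher in Capan1, the ErbB pathway has 3 genes, EREG, TGFA and HBEGF, with a Benjamini-adjusted p of 0.689, and 0 of its 6 terms were under 0.05.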
